A study of Homo sapiens with 18 samples.

How the data were processed

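Polyadenylated RNA was measured by sequencing in hTERT-RPE1 cells, an established, near-diploid line of human retinal pigment epithelium immortalised with telomerase. The cells were untreated, treated with cytochalasin D, which blocks actin polymerisation and with it cytokinesis, or treated with ZM447439, an inhibitor of Aurora kinases. Per the labels' protocols, cells were grown in medium with 10% serum, ZM447439 was given at 2.5 µM for 24 h, and DNA was stained with Hoechst at 2 µg/mL for 60 min before flow sorting into populations with 2N and 4N DNA content. The labels carry the same treatment text on every library and give no dose or time for cytochalasin D. The series design names 3 biological replicates for each of the 6 groups, which makes 18 libraries. The kit did not mark strand.

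The authors deposited 1 table of RPKM values, read numbers scaled by library size and gene length, for 57773 Ensembl gene identifiers in the 18 libraries. Per the submitters' processing notes, the tools used before deposit included CASAVA 1.8.2, TopHat2 and edgeR, with the hg19 build; the notes give no order or settings, and the read counter is not given in the sources used here. Symbols were found for 52338 identifiers (90.6%) in a table of gene names and in GENCODE 29, and no coordinates of that annotation are printed because it belongs to another build. The table held no negative and no missing values.

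The length behind the deposited RPKM was tested on low values, those worth under 200 reads. With the genomic span of the gene, introns included, 88.8% to 89.4% of these values in genes with several exons came out as whole reads within 0.05 reads. With the summed exon length the share was 11.9% to 12.8%, near the 10% that chance gives at this tolerance. The values were therefore read as reads divided by the whole span, so that a long gene has a far lower RPKM than its number of reads would give with exon length. The implied library sizes were 51135642 to 78294394 reads, and the reads summed over genes came to 0.97 to 1.13 times that size. A sum above the size cannot arise from a plain total of reads each counted once, so the implied size may differ from the true depth. Each library's depth was taken from these steps. At the median depth, a gene with a span of 100 kb that just passed the filter below held about 2920 reads, and a shorter one fewer. Of 12135 tested genes with a span, 13.6% held under 100 reads per library on average. Counting error, taken as Poisson, made up more than 50% of the residual variance in 18.5% of these genes.

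Genes with a mean of at least 0.5 RPKM over the 18 libraries were tested: 13037 genes (22.6% of the table), among them 7750 of the 18472 protein-coding genes with any value above 0. The filter left out many long genes. RPKM values are not counts, so log2(RPKM + 0.5) was analysed with limma 3.58.1 in R 4.3.3. One mean was fitted per group over all 18 libraries, which gave 12 residual degrees of freedom, and the spread was moderated with a trend on the mean level (prior degrees of freedom 2.02). Tests were two-sided, with Benjamini-Hochberg (BH) adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(RPKM + 0.5) scale and understate the change of genes of low level; errors of fold changes are standard errors (SE) from limma, errors of levels are SD with n = 3. In the 11 comparisons, 4N cells were compared with 2N cells within each treatment, each drug with untreated cells within each sort, and the 2 drugs with each other in 4N cells; 3 interactions tested whether the difference between 4N and 2N cells differed between treatments.

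Before the data were examined, 20 gene lists with 634 genes were fixed: p53 targets, G2/M genes, G1/S and replication genes, G1 cyclins with CDKs and CDK inhibitors, SRF-MRTF and actin cytoskeleton genes, YAP-TEAD targets, immediate early genes, NF-kB and secreted inflammatory genes, interferon-stimulated genes, ER stress and ATF4 genes, heat shock genes, cholesterol synthesis genes, lysosome and autophagy genes, extracellular matrix genes, glycolysis and hypoxia genes, ribosomal protein genes, mitochondrially encoded transcripts, replication-dependent histone genes, retinal pigment epithelium markers and blood cell markers. Lists were tested with limma's camera at a preset correlation between genes of 0.01, BH-adjusted over the lists of a comparison. Beside it stood camera with an estimated correlation and fry, which tests whether a list's genes move on balance in one direction. Of the 17 blood cell markers only CD68, a lysosomal protein that other cells also make, passed the filter; its mean was 19.7 RPKM in untreated 2N cells, and the list was not tested. Some genes stand in more than 1 list. For replication-dependent histone genes only polyadenylated transcripts were measured, which need not follow the whole output of these genes.

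Genes named in the text were selected by a rule fixed before the data were examined. For the 5 main comparisons (4N against 2N in each treatment, and each drug against untreated 4N cells) it took the 8 largest increases and 8 largest decreases among genes past the threshold, with a mean of at least 2 RPKM in the higher group and no overlap between the 3 values of each group. It added up to 2 called members per list and direction, and 12 genes in every comparison. The other comparisons used 5 in place of 8. Some genes that the rule selects are not reported here. Groups of 3 fail to overlap by chance for 10% of unchanged genes, and an exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so p-values rest on the model across genes. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart; CCNE2, CCNF, MDM2, PLK1, VEGFA, ITGA10, XPC, DDIT4, HMGCS1, RDH5, KRT8 and the neighbours HSPD1 and HSPE1 share exon bases with an annotated gene of similar or higher RPKM, and their levels are uncertain to that extent. PMEL and SQSTM1 overlap an opposite-strand gene of higher RPKM (CDK2 and MGAT4B) outside their exons, and are uncertain too, as the read counter is not known. The same holds for genes with near-identical copies (ACTB, ACTG1, ribosomal protein and histone genes), as reads could be split between copies.

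The tests were checked on simulated values drawn from the real spread of 12135 genes. For untreated 4N against 2N cells, 74.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 0.08% of unchanged genes were called. For cytochalasin D the shares were 70.1%, 91.0% and 100%, and 0.13% of unchanged genes were called. The simulated noise was independent between libraries, without the 2 sets of libraries described at the end, and the changed genes were drawn at random. The shares therefore need not hold in the real libraries, or for genes with a wide spread such as CDKN1A (SE 0.55) and MDM2 (SE 0.38).

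Whether replicate numbers pair the libraries was decided from the correlation, across genes, of deviations from the group means, before the fits were compared. Libraries of the same treatment and number correlated at 0.19, 0.19 and 0.45 (untreated), 0.63, 0.33 and 0.40 (cytochalasin D) and 0.44, 0.28 and 0.26 (ZM447439), all above 0.1. The 2N and 4N libraries of a treatment were therefore taken as paired by number. The best partner did not always carry the same number: untreated libraries 1 and 2 were exchanged, and ZM447439 2N library 2 correlated best with 4N library 3. Unlike numbers correlated as highly in places (0.26 for untreated 2N library 1 with 4N library 2, 0.39 for cytochalasin D 2N library 3 with 4N library 2). Pairing by number was clear only for untreated libraries 3 and drug libraries 1, which stood apart from their groups. For the other numbers it was assumed. The 2 drugs also correlated by number (0.48, 0.23 and 0.31 in 2N cells; 0.52, 0.25 and 0.31 in 4N cells), while untreated libraries numbered 2 correlated negatively with those of both drugs (-0.09 and -0.07 for cytochalasin D, -0.21 and -0.15 for ZM447439), so numbers did not pair untreated with treated cells. A block by culture, meaning treatment and number, was added for this reason after the data were seen. In comparisons of a drug with untreated cells, the planned block by number over all libraries joined libraries that were not paired.

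Alternatives fixed beforehand were pseudocounts of 0.1 and 1, no filter or a mean of at least 2 RPKM, rescaling of each library to a common median ratio, quantile normalization, a fit of the compared libraries alone, the replicate number as a block over all libraries, and leaving out each library in turn. Alternatives added after the data were seen were RPM in place of RPKM (the division by span undone, 20106 genes tested), the culture block, both together, a block of 2 sets of libraries seen in the data, and fits without libraries that stood apart from their group.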

Results

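RNA levels were compared between hTERT-RPE1 cells sorted for 2N and 4N DNA content after no treatment, cytochalasin D or ZM447439, with 3 libraries in each of the 6 groups. A 4N content is held by diploid cells in G2 or mitosis and by tetraploid cells in G1, and the series concerns polyploid cells made by failed cytokinesis or by Aurora kinase inhibition. Implied library sizes, from the steps of the deposited RPKM values, were 51135642 to 78294394 reads. In all, 13037 genes were tested. The main axis of variation held 67.1% of the variance. Levels below are RPKM over the genomic span as mean ± SD (n = 3), and fold changes are log2 with the SE from limma. RPKM are scaled to the size of a library, so rises and falls are relative and do not give RNA per cell. Every adjusted p is from limma with BH adjustment, or for a list from limma's camera with BH adjustment over lists. Of 209 list tests without a block, 88 passed at the preset correlation and 0 passed with an estimated correlation (lowest adjusted p = 0.227). Each list result below therefore rests on the preset value, except 2 with culture as a block that are named below.

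In untreated cells, where the 4N sort collects cells in G2 and mitosis, genes of the G2/M programme rose. UBE2C, an ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose from 5.80 ± 2.05 in 2N to 47.4 ± 0.938 RPKM in 4N cells (log2 change 2.99, SE 0.28, adjusted p = 4.01e-06). TOP2A, which untangles DNA before mitosis, rose by 2.40 (SE 0.18), CDK1, the mitotic kinase, by 2.36 (SE 0.25), and the cyclin F gene CCNF by 2.04 (SE 0.11). The centromeric histone chaperone gene HJURP rose by 2.19 (SE 0.19), and FAM83D by 2.25 (SE 0.17). Both Aurora kinase genes rose, AURKA by 1.85 (SE 0.19) and AURKB by 1.78 (SE 0.18). Of the 49 G2/M genes tested, 47 rose and 0 fell, and 49 rose when adjusted over the list alone. The median was 1.45 with adjusted p = 1.68e-43, or adjusted p = 0.35 with an estimated correlation.

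Several genes of the G1/S transition were lower in untreated 4N cells. UNG, which removes uracil from DNA, fell by 1.75 (SE 0.09, adjusted p = 3.89e-08), CCNE2, a cyclin of S-phase entry, fell by 1.41 (SE 0.08), and FAM111B fell by 1.25 (SE 0.05). E2F1, a transcription factor of S-phase genes, fell by 0.81 (SE 0.07), from 6.71 ± 0.501 to 3.62 ± 0.397 RPKM. Of 32 G1/S and replication genes, 4 rose and 16 fell, with 5 and 16 when adjusted over the list alone (median -0.26, adjusted p = 3.21e-10, and adjusted p = 0.491 with an estimated correlation). Among 15 G1 cyclins, CDKs and CDK inhibitors, 3 rose and 2 fell (5 and 2 adjusted over the list alone). The CDK4 and CDK6 inhibitor genes CDKN2D and CDKN2C rose by 1.79 (SE 0.11) and 1.18 (SE 0.09). The chemokine gene CCL2 fell by 1.30 (SE 0.15), 1 of 3 NF-kB and secreted inflammatory genes that fell among 14 tested, with 3 adjusted over the list alone (adjusted p = 0.0093, and adjusted p = 0.491 with an estimated correlation). Among 10 replication-dependent histone genes 2 fell, and 3 adjusted over the list alone (adjusted p = 0.0408, and adjusted p = 1 with an estimated correlation). CDKN1A, the p53 target that encodes p21, differed by 0.25 (SE 0.55, adjusted p = 0.836), MDM2, which encodes the p53 ubiquitin ligase, by 0.19 (SE 0.38), and CCND1, the cyclin D1 gene, by 0.25 (SE 0.26). None of these 3 passed.

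In all, 1679 genes rose and 593 fell in untreated 4N cells, 113 and 24 of them by 2-fold or more. After rescaling to a common median ratio the split was 1186 up and 847 down, and after quantile normalization it was 1033 and 664. Without both untreated libraries numbered 3, which stood apart from the others of their groups, 1218 genes passed, and without the 6 libraries that stood apart in all groups 3915 passed. With culture as a block, immediate early genes (down, adjusted p = 0.000717, and adjusted p = 0.413 with an estimated correlation) and SRF-MRTF and actin genes (up, adjusted p = 0.0107, and adjusted p = 0.962 with an estimated correlation) also passed in camera.

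Under cytochalasin D, no gene passed between 4N and 2N cells (limma, 0 of 13037 genes), and 682 genes had an unadjusted p under 0.05, where 652 are expected by chance. A block by culture, which takes the sorts as paired by number, gave 1411 genes at an unadjusted p under 0.05, and 2511 of 20106 with RPM and that block. MKI67, the proliferation marker Ki-67, was 2.55 ± 0.319 RPKM in 4N and 1.25 ± 0.549 in 2N cells (log2 difference 0.84, SE 0.24, adjusted p = 0.649). CCNB1, which encodes cyclin B1, differed by 0.71 (SE 0.23, adjusted p = 0.739), AURKB by 0.59 (SE 0.18) and AURKA by 0.44 (SE 0.19). As a group the 49 G2/M genes were higher in 4N cells, with a median of 0.44 and 39 members passing when adjusted over the list alone (adjusted p = 2.37e-44, and adjusted p = 0.333 with an estimated correlation). The p53 targets also ranked higher (median 0.19, adjusted p = 0.000262) and the cholesterol synthesis genes lower (median -0.30, adjusted p = 0.000262), with adjusted p = 0.72 for both with an estimated correlation and 0 members passing when adjusted over the list alone. Lysosome and autophagy genes ranked lower as well (median -0.10, adjusted p = 0.000577, and adjusted p = 0.72 with an estimated correlation). CDKN1A differed by 0.39 (SE 0.55) and MDM2 by 0.35 (SE 0.38), and neither passed.

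With culture as a block, chosen after the data were seen, 12 p53 targets were higher and 1 lower under cytochalasin D when adjusted over the list alone (camera adjusted p = 2.72e-13, and adjusted p = 0.0727 with an estimated correlation). Of 19 YAP-TEAD targets 11 were lower and 1 higher over the list alone (camera adjusted p = 1.4e-08; 0.0192 without the block), and of 25 immediate early genes 14 were lower and 0 higher (2.2e-12; 0.0122 without the block). Both lists also passed in this fit with an estimated correlation (adjusted p = 0.0408 for each). Of the G2/M genes 3 passed over the list alone in this fit (adjusted p = 0.245 with an estimated correlation).

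The count under cytochalasin D was 13 with no filter, 1 in a fit of its own 6 libraries, 3 with culture as a block, and 126 with RPM and culture as a block. It was 941 without the 6 libraries that stood apart in all groups, but 0 without both cytochalasin D libraries numbered 1, and 5 without cytochalasin D 2N replicate 1. In the first of these fits 2 near-alike libraries per group remained, so its spread may understate that between cultures.

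Under ZM447439, genes of the G2/M programme were again higher in 4N cells. KIF20A, a kinesin of cytokinesis, rose from 1.58 ± 1.10 to 8 ± 2.48 RPKM (log2 change 2.11, SE 0.28, adjusted p = 0.00181). CDC20, an activator of the anaphase-promoting complex, rose by 1.74 (SE 0.28), the mitotic kinase gene PLK1 by 1.72 (SE 0.25), the securin gene PTTG1 by 1.54 (SE 0.21), the survivin gene BIRC5 by 1.51 (SE 0.22) and CCNB1 by 1.5 (SE 0.23). Of the 49 G2/M genes, 42 rose and 0 fell, with 48 up when adjusted over the list alone (median 0.79, adjusted p = 9.84e-34, and adjusted p = 0.644 with an estimated correlation). CCNE2 fell by 0.40 (SE 0.08, adjusted p = 0.00806). Of 28 SRF-MRTF and actin cytoskeleton genes, 6 fell and 0 rose, with 15 down and 1 up when adjusted over the list alone (median -0.29, adjusted p = 2.49e-07, and adjusted p = 0.764 with an estimated correlation). PDLIM7, which binds actin filaments, fell by 0.48 (SE 0.11), and ACTG1, the gamma-actin gene, fell by 0.31 (SE 0.06, adjusted p = 0.0124; 0.073 after quantile normalization).

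Among p53 targets under ZM447439, 2 of 27 rose and 0 fell (2 and 0 adjusted over the list alone): XPC, a DNA damage sensor, by 0.60 (SE 0.15) and the cyclin G1 gene CCNG1 by 0.45 (SE 0.13, adjusted p = 0.0429; 0.053 after rescaling). The list median was 0.43 (adjusted p = 1.41e-05, and adjusted p = 0.764 with an estimated correlation). With RPM, 3 of 38 rose and 0 fell, 14 and 0 over the list alone (median 0.66). CDKN1A was 78.1 ± 38.6 RPKM in 4N and 38.2 ± 34.2 in 2N cells (log2 difference 1.26, SE 0.55, adjusted p = 0.172), and MDM2 differed by 1.08 (SE 0.38, adjusted p = 0.0976). With culture as a block, pairing the sorts by number, both passed (limma, adjusted p = 0.0067 for CDKN1A and 0.0069 for MDM2). Without ZM447439 2N replicate 1, CDKN1A and MDM2 differed by 1.94 (adjusted p = 0.011) and 1.65 (adjusted p = 0.001). That fit kept 4N replicate 1, which stood apart as well, so the removal was not balanced between the sorts. Of 25 lysosome and autophagy genes 5 fell, 11 down and 1 up when adjusted over the list alone (median -0.20, adjusted p = 7.71e-06, and adjusted p = 0.764 with an estimated correlation). The cholesterol synthesis genes had a median of -0.52 with 0 of 24 members passing (adjusted p = 3.44e-06, and adjusted p = 0.764 with an estimated correlation). More members passed with culture as a block: 20 p53 targets rose and 0 fell (adjusted p = 0.273 with an estimated correlation), and 13 cholesterol synthesis genes fell, 23 adjusted over the list alone (adjusted p = 0.458 with an estimated correlation). In the same fit 20 SRF-MRTF and actin genes fell and 1 rose, and 13 of 23 extracellular matrix genes fell and 0 rose (adjusted p = 0.458 for both with an estimated correlation), against 1 extracellular matrix gene without the block.

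In all, 679 genes rose and 319 fell under ZM447439, 33 and 1 of them by 2-fold or more. The split was 590 and 423 after rescaling to a common median ratio and 636 and 512 after quantile normalization. This count depended on the libraries: 0 genes passed when its own 6 libraries were fitted alone (2162 at an unadjusted p under 0.05), 208 without ZM447439 2N replicate 2, 2722 without ZM447439 2N replicate 1, and 2019 with culture as a block. Without ZM447439 2N replicate 2, ACTG1, PDLIM7, XPC and CCNG1 did not pass (limma, adjusted p = 0.0622, 0.0809, 0.138 and 0.189), nor did they without 2N replicate 3, 4N replicate 2 or 4N replicate 3, and XPC and CCNG1 also not without 4N replicate 1 (0.0701 and 0.105).

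The differences between 4N and 2N cells were compared between treatments by interaction tests. UNG fell in untreated 4N cells, and its difference between 4N and 2N cells was higher with drug by 1.65 (SE 0.13, adjusted p = 1.03e-05) for cytochalasin D and 1.59 (SE 0.13, adjusted p = 1.8e-05) for ZM447439. The rise of CCNF was smaller with drug by -1.67 (SE 0.16) and -1.68 (SE 0.16), and that of CDKN2D by -1.71 (SE 0.16) and -1.60 (SE 0.16). CCNF averaged 1.09 RPKM over all libraries, so its differences are understated in groups where its level is low. Under cytochalasin D, 35 of 49 G2/M genes had a lower and 0 a higher difference than untreated cells, with 40 lower when adjusted over the list alone (median -0.96, adjusted p = 1.05e-26, and adjusted p = 0.523 with an estimated correlation). With RPM, 13 of 55 were lower and 0 higher, 27 lower over the list alone (median -0.79). Under ZM447439, 28 were lower and 2 higher (30 and 3 adjusted over the list alone; median -0.67, adjusted p = 6.41e-11, and adjusted p = 0.919 with an estimated correlation). With RPM, 12 of 55 were lower and 2 higher, 16 and 3 over the list alone (median -0.49). Over all genes, 1023 differed for cytochalasin D (235 up, 788 down; 333 and 526 after rescaling) and 1317 for ZM447439 (459 up, 858 down; 569 and 646 after rescaling). Without ZM447439 2N replicate 1 the second count was 2429, without ZM447439 4N replicate 3 it was 784, and with culture as a block the counts were 1924 and 2505.

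Between the 2 drugs no gene passed in the interaction test (limma, 0 of 13037; 753 at an unadjusted p under 0.05), although 267 passed without ZM447439 2N replicate 1, 443 without both ZM447439 libraries numbered 1 and 1621 without the 6 libraries that stood apart. Across genes, the 4N against 2N changes under the 2 drugs, which share no library, correlated at r = 0.54, and 70.3% had the same sign. By number, the correlation was 0.07, 0.38 and 0.42. The change under ZM447439 correlated with that of untreated cells at r = 0.26, with 239 genes up in both (87.5 for independent lists), 27 down in both (14.5) and 52 opposite. Genes are not independent replicates, so these correlations carry no p.

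**Figure D1:**
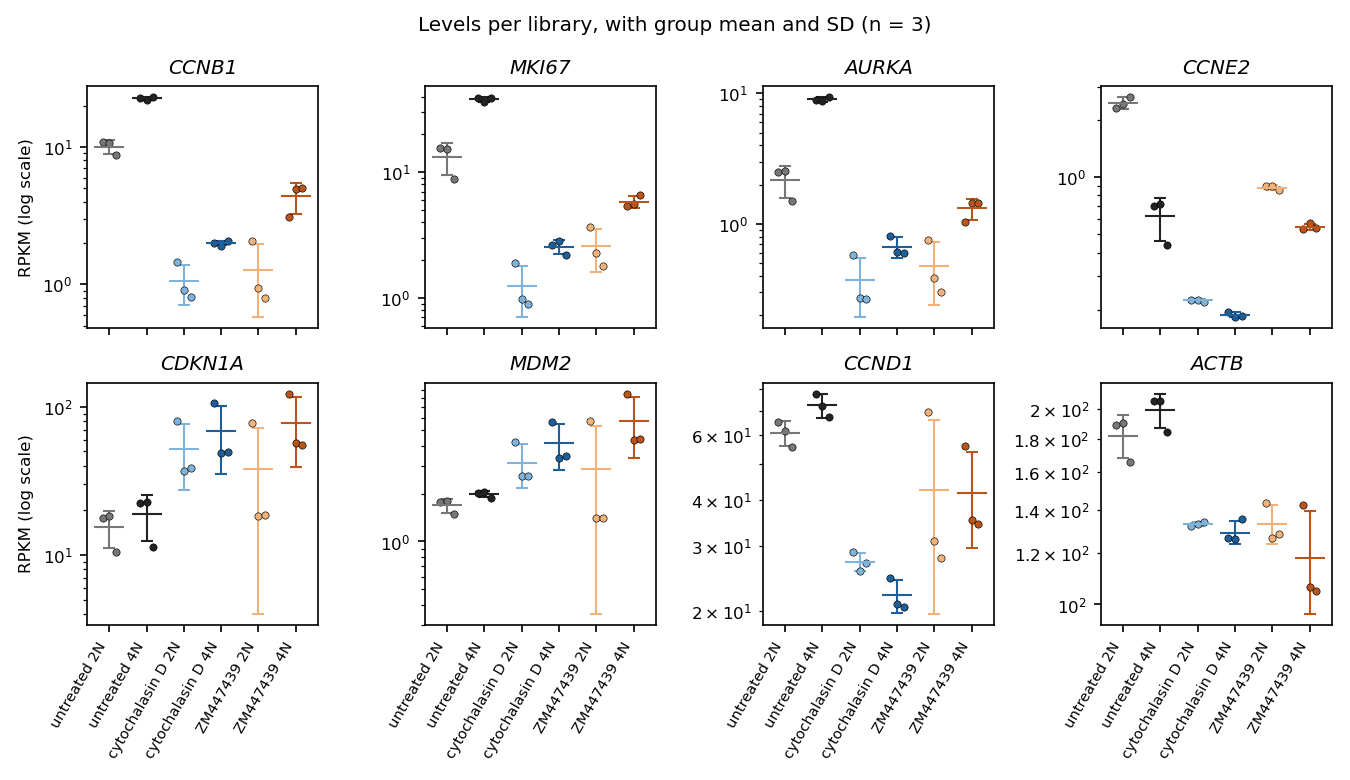
RPKM of 8 genes named in every comparison, on a log scale, for each of the 18 libraries (points), with the group mean (wide bar) and SD (n = 3). CCNB1 means run from 1.05 RPKM in cytochalasin D 2N to 22.7 RPKM in untreated 4N cells, and in both ZM447439 groups 1 library lies above the other 2 for CDKN1A, MDM2 and CCND1.

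Against untreated 4N cells, cytochalasin D 4N cells had lower levels of nearly all genes of both cell-cycle lists. The untreated 4N sort collects cells in G2 and mitosis. This comparison and that of ZM447439 may therefore hold differences in cell-cycle phase, which was not measured. RRM2, a subunit of ribonucleotide reductase, fell from 53 ± 2.08 to 2.91 ± 0.0752 RPKM (log2 change -3.97, SE 0.20, adjusted p = 3.87e-10). CCNA2, the cyclin A2 gene, fell by 3.88 (SE 0.20), UBE2C by 3.78 (SE 0.28), MKI67 by 3.66 (SE 0.24), TCF19 by 3.56 (SE 0.15) and ZWINT, a kinetochore gene, by 3.52 (SE 0.14). All 49 G2/M genes fell (median -2.82, adjusted p = 1.25e-15), and 31 of 32 G1/S and replication genes fell (median -1.73, adjusted p = 1.05e-13), the same numbers as when adjusted over the list alone. For both, adjusted p = 0.501 with an estimated correlation, and with RPM the medians were -3.52 and -2.75. FEN1, a nuclease of lagging-strand synthesis, fell by 3.00 (SE 0.07) and E2F1 by 2.26 (SE 0.07). Among G1 cyclins, CDKs and CDK inhibitors 5 rose and 9 of 15 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.348, 0.00917 with RPM). CCND1 fell by 1.70 (SE 0.26), and CDKN1C, which encodes the CDK inhibitor p57, rose by 1.66 (SE 0.22).

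Among the genes that rose most with cytochalasin D were CHI3L1, a secreted chitinase-like protein, from 0.526 ± 0.218 to 23.9 ± 4.84 RPKM (log2 change 4.57, SE 0.34, adjusted p = 1.81e-08), the integrin gene ITGA10 (3.04, SE 0.10), the secretogranin gene SCG2 (2.99, SE 0.27) and DDIT4L, a regulator of mTOR (2.91, SE 0.23). Of 27 p53 targets 17 rose and 1 fell, also when adjusted over the list alone (median 0.64, adjusted p = 0.000305, and adjusted p = 0.673 with an estimated correlation). CDKN1A rose by 1.79 (SE 0.55, adjusted p = 0.00884) and BTG2, an antiproliferative p53 target, by 1.95 (SE 0.41), while MDM2 did not pass (0.87, SE 0.38, adjusted p = 0.0555; 0.034 after rescaling). Of 13 interferon-stimulated genes 11 rose and 1 fell, also adjusted over the list alone (median 0.96, adjusted p = 0.000153, and adjusted p = 0.501 with an estimated correlation). IFIT2 rose by 1.79 (SE 0.10) and IRF9, a subunit of the interferon response factor, by 1.51 (SE 0.13), while OAS3 fell by 0.68 (SE 0.08). Of 25 lysosome and autophagy genes 21 rose and 2 fell, also adjusted over the list alone (median 0.71, adjusted p = 1.65e-07, and adjusted p = 0.501 with an estimated correlation), among them GABARAPL1 (1.90, SE 0.12) and the autophagy receptor gene SQSTM1 (1.69, SE 0.28). Of 14 NF-kB and secreted inflammatory genes 8 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.501 with an estimated correlation). CCL2 rose by 1.91 (SE 0.15) and IL1B by 1.68 (SE 0.20).

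Other groups moved in mixed or opposite directions with cytochalasin D. Of 20 heat shock genes 13 fell and 0 rose, also adjusted over the list alone (median -0.93, adjusted p = 0.00795, and adjusted p = 0.673 with an estimated correlation), with HSP90AA1 down by -1.55 (SE 0.14) and HSPD1, a mitochondrial chaperonin, by -1.48 (SE 0.12). ACTB, the beta-actin gene, fell by 0.62 (SE 0.10) while ACTG1 did not pass (0.04, SE 0.06; 0.17 and adjusted p = 0.031 after rescaling). Of 28 SRF-MRTF and actin cytoskeleton genes 2 rose and 12 fell (2 and 11 adjusted over the list alone; camera adjusted p = 0.495), and ACTN1, an actin crosslinker, fell by 1.02 (SE 0.14). Of 19 YAP-TEAD targets 3 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.288), with FJX1 at -2.15 (SE 0.10) and IGFBP3 at -2.42 (SE 0.47). Of 23 ER stress and ATF4 genes 3 rose and 13 fell, also adjusted over the list alone (camera adjusted p = 0.495). DDIT4, an mTOR inhibitor, rose by 2.41 (SE 0.26), and the one-carbon and serine synthesis genes MTHFD2 and PSAT1 fell by 2.09 (SE 0.14) and 2.02 (SE 0.22). Of 23 extracellular matrix genes 7 rose and 3 fell (7 and 2 adjusted over the list alone; adjusted p = 0.04, 0.0644 with the replicate block, 0.0707 with RPM, and adjusted p = 0.806 with an estimated correlation). The fibronectin gene FN1 rose by 1.49 (SE 0.24) and the collagen-crosslinking enzyme gene LOX fell by 1.18 (SE 0.23). Of 24 cholesterol synthesis genes 1 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.495). TM7SF2 rose by 2.26 (SE 0.25).

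In all, 3398 genes rose and 5793 fell with cytochalasin D in 4N cells, 560 and 1131 of them by 2-fold or more. The median over all genes was -0.13, and after rescaling to a common median ratio 4487 rose and 4584 fell. Of 73 ribosomal protein genes 59 fell and 0 rose, also adjusted over the list alone (median -0.25, adjusted p = 0.000305, and adjusted p = 0.673 with an estimated correlation). After quantile normalization the list pointed up (adjusted p = 0.922). The libraries of each group were parted into 2 sets, taken as shared unequally by treated and untreated groups, as described at the end. Within each set the median was -2.65 and -2.89 for G2/M genes, 0.98 and 0.61 for p53 targets, and 1.13 and 0.94 for interferon-stimulated genes. It differed in sign for cholesterol synthesis genes (-0.43 and 0.23) and extracellular matrix genes (0.65 and -0.06). The fold changes of the 2 sets correlated at r = 0.90 across genes.

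Against untreated 4N cells, ZM447439 4N cells also had lower cell-cycle genes. UBE2C fell from 47.4 ± 0.938 to 6.37 ± 0.472 RPKM (log2 change -2.80, SE 0.28, adjusted p = 1.01e-06), PLK1 fell by 2.69 (SE 0.25), CDCA8, a subunit of the chromosomal passenger complex with AURKB, by 2.61 (SE 0.19), AURKB by 2.50 (SE 0.18) and AURKA by 2.40 (SE 0.19). All 49 G2/M genes fell (median -2.15, adjusted p = 3.37e-21), and of 32 G1/S and replication genes 30 fell and 1, UNG, rose (median -1.03, adjusted p = 2.39e-14), with the same numbers adjusted over the list alone. For both, adjusted p = 0.554 with an estimated correlation. UNG rose by 0.33 (SE 0.09). RRM2 fell by 2.20 (SE 0.20) and CDT1, which licenses replication origins, by 1.56 (SE 0.10). Of 15 G1 cyclins, CDKs and CDK inhibitors 4 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.168, 0.0109 with RPM), with CDKN2D at -1.98 (SE 0.11) and CCND1 at -0.81 (SE 0.26, adjusted p = 0.0163).

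Genes of the p53 response rose with ZM447439. Of 27 targets 20 rose and 0 fell, with 21 up when adjusted over the list alone (median 0.73, adjusted p = 1.05e-06, and adjusted p = 0.571 with an estimated correlation). CDKN1A rose from 18.9 ± 6.49 to 78.1 ± 38.6 RPKM (log2 change 1.98, SE 0.55, adjusted p = 0.00664), BTG2 by 1.94 (SE 0.41) and MDM2 by 1.26 (SE 0.38, adjusted p = 0.0116; 0.97 and adjusted p = 0.059 without ZM447439 4N replicate 1). RRAD, a small GTPase, rose by 2.25 (SE 0.16), PIK3IP1, an inhibitor of PI3 kinase, by 1.92 (SE 0.14), and CCL2 by 1.93 (SE 0.15). Of 25 lysosome and autophagy genes 17 rose and 1 fell, also adjusted over the list alone (median 0.33, adjusted p = 5.74e-06, and adjusted p = 0.554 with an estimated correlation). Of 13 interferon-stimulated genes 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0149, and adjusted p = 0.591 with an estimated correlation), with IFIT2 at 0.95 (SE 0.10) and STAT2 at 0.84 (SE 0.11). Of 20 heat shock genes 14 fell and 0 rose, also adjusted over the list alone (median -0.62, adjusted p = 0.0145, and adjusted p = 0.807 with an estimated correlation). HSPA8 fell by 1.19 (SE 0.13). Of 28 SRF-MRTF and actin cytoskeleton genes 2 rose and 14 fell (2 and 15 adjusted over the list alone; camera adjusted p = 0.0615, 0.0196 with the replicate block, 0.0329 with RPM), with ACTB at -0.76 (SE 0.10) and ACTG1 at -0.51 (SE 0.06).

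In all, 2560 genes rose and 4630 fell with ZM447439 in 4N cells (163 and 429 by 2-fold or more), and 3472 and 3654 after rescaling. Within the 2 sets of libraries the G2/M median was -2.23 and -2.12, the p53 median 1.10 and 0.63 and the heat shock median -0.67 and -0.44. CCND1 did not pass without untreated 4N replicate 1 (-0.76, adjusted p = 0.051), without ZM447439 4N replicate 2 (-0.71, adjusted p = 0.062) or without ZM447439 4N replicate 3 (-0.69, adjusted p = 0.067), and UNG did not pass in a fit of these 6 libraries alone (adjusted p = 0.062).

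**Figure D2:**
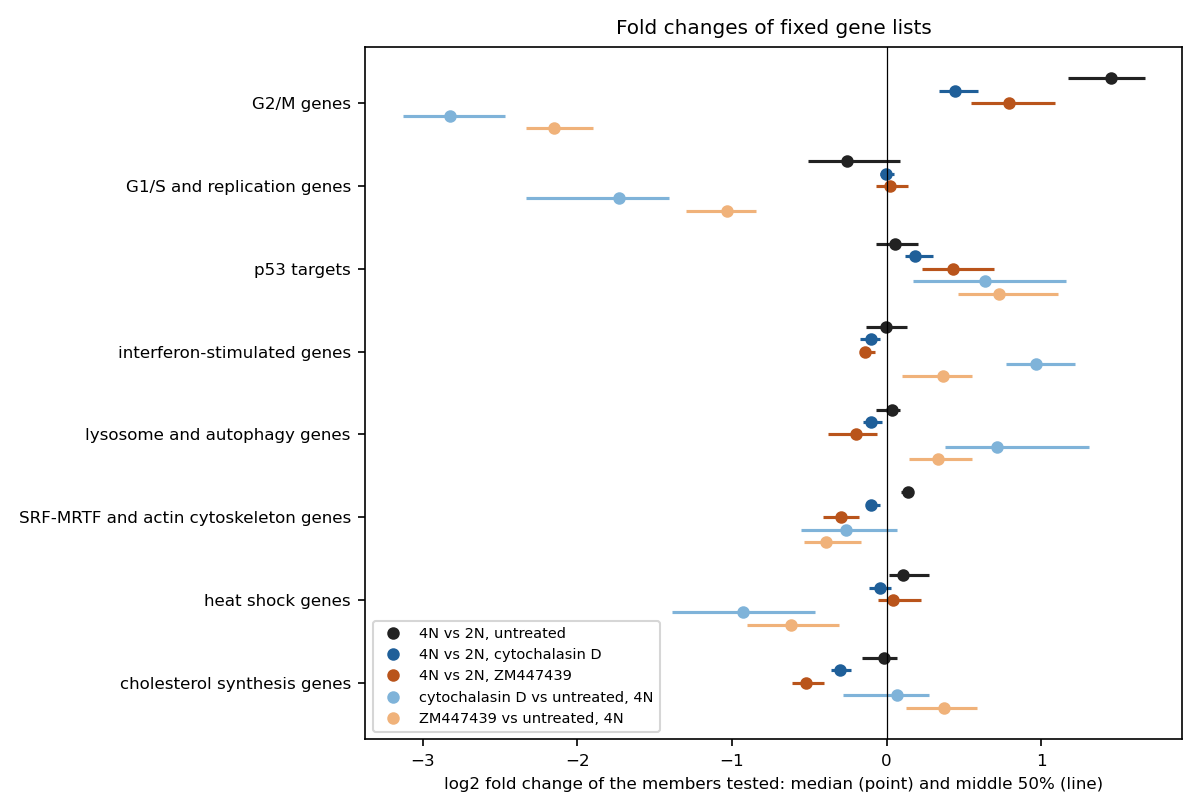
Median log2 fold change (point) and middle 50% (line) of the tested members of 8 gene lists in the 5 main comparisons. The median of the G2/M genes is 1.45, 0.44 and 0.79 for 4N against 2N cells in untreated, cytochalasin D and ZM447439 cells, and -2.82 and -2.15 for each drug against untreated 4N cells. With RPM, which undoes the division by span, these medians are 1.63, 0.89, 1.2, -3.52 and -2.51, so the size of the drop under the drugs in the first 3 depends on the scale.

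The 2 drugs shared most of their calls in 4N cells: 2207 genes rose in both (667 for independent lists), 4248 fell in both (2057) and 65 moved in opposite directions. The fold changes correlated at r = 0.89 with a covariance of 0.30. Both drugs were set against the same 3 untreated libraries, and unchanged groups simulated against them gave r = 0.49, a covariance of 0.01 and 0 shared calls. The covariance by number was 0.32, 0.31 and 0.32. Shared controls add the same covariance with or without effects, so the covariance above the simulated one is not from them. That covariance also holds any effect of the unequal sets of libraries described at the end. The untreated 4N sort collects cells in G2 and mitosis, whereas 4N cells with drug may include tetraploid cells in G1. A difference in cell-cycle phase from the common control may therefore be part of it, and phase was not measured. The simulated covariance was at most 0.0116 against 0.296 observed, which argues against shared controls as a large part of r. With 3 controls no parts of 2 libraries each could be formed, so part of the excess in shared calls may come from the shared controls.

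Compared directly in 4N cells, cytochalasin D had lower cell-cycle genes than ZM447439. RRM2 was lower by -1.77 (SE 0.20, adjusted p = 1.34e-05), at 2.91 ± 0.0752 against 11.1 ± 1.07 RPKM, and FEN1 by -1.51 (SE 0.07) and CCNA2 by -1.38 (SE 0.20). All 32 G1/S and replication genes were lower (median -0.72, adjusted p = 1.79e-18, and adjusted p = 0.301 with an estimated correlation), as were 45 of 49 G2/M genes (median -0.64, adjusted p = 5.94e-08, and adjusted p = 0.821 with an estimated correlation), with the same numbers adjusted over the list alone. With RPM these medians were -1.35 and -1.02. Of 19 YAP-TEAD targets 9 were lower and 3 higher, 10 and 3 adjusted over the list alone (camera adjusted p = 0.177, 0.0367 with the replicate block, 0.0211 with RPM). ANKRD1 was lower by -2.72 (SE 0.37) and the tissue factor gene F3 by -1.65 (SE 0.28). The Wnt antagonist gene DKK1 was lower by -2.02 (SE 0.10), AMIGO2 by -2.01 (SE 0.22) and CCND1 by -0.88 (SE 0.26; -0.66 and adjusted p = 0.069 without ZM447439 4N replicate 1).

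Higher with cytochalasin D than with ZM447439 were CHI3L1 (3.57, SE 0.34), ITGA10 (2.40, SE 0.10), the matrix protease gene MMP14 (1.25, SE 0.07) and FN1 (1.30, SE 0.24). Of 13 interferon-stimulated genes 11 were higher and 0 lower (median 0.60, adjusted p = 1.78e-06, and adjusted p = 0.373 with an estimated correlation), and of 25 lysosome and autophagy genes 13 were higher and 1 lower, with 14 and 1 adjusted over the list alone (adjusted p = 1.78e-06, and adjusted p = 0.807 with an estimated correlation). The lysosomal activator gene PSAP was higher by 0.80 (SE 0.13). ACTG1 was higher by 0.55 (SE 0.06), while CDKN1A differed by -0.19 (SE 0.55) and MDM2 by -0.40 (SE 0.38), neither of which passed. In all, 2050 genes were higher and 3622 lower, and 2693 and 2894 after rescaling. Doses and times of the 2 drugs are not both given, so the drugs were not compared at matched doses.

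In 2N cells both drugs lowered the cell-cycle lists. With cytochalasin D all 32 G1/S and replication genes and 48 of 49 G2/M genes fell, with the same numbers adjusted over the list alone (medians -1.95 and -1.82; adjusted p = 2.53e-18 and 8.57e-13, and adjusted p = 0.307 and adjusted p = 0.692 with an estimated correlation). With RPM the medians were -3.14 and -2.75. The replication licensing gene CDC6 fell from 6.46 ± 0.389 to 0.303 ± 0.05 RPKM (log2 change -3.12, SE 0.08, adjusted p = 1.12e-12), and CCNE2 fell by 2.03 (SE 0.08). CHI3L1 rose by 4.80 (SE 0.34), the lysosomal glucosidase gene GAA by 1.61 (SE 0.10), and the p53 target TP53INP1 by 1.52 (SE 0.11). CDKN1A rose by 1.65 (SE 0.55, adjusted p = 0.0151), but without untreated 2N replicate 3 (1.40, adjusted p = 0.061) or cytochalasin D 2N replicate 1 (1.29, adjusted p = 0.07) it did not pass. Within the 2 sets of libraries the cholesterol median was -0.42 and 0.48. In all, 3539 genes rose and 5149 fell, and 4401 and 4336 after rescaling.

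With ZM447439 in 2N cells, 32 of 32 G1/S and replication genes and 48 of 49 G2/M genes fell, with the same numbers adjusted over the list alone (medians -1.28 and -1.35; adjusted p = 1.74e-20 and 1.14e-15, and adjusted p = 0.227 and adjusted p = 0.579 with an estimated correlation). With RPM the medians were -1.64 and -2.15. KIF20A fell by 3.48 (SE 0.28, adjusted p = 2.04e-07) and CDC20 by 3.09 (SE 0.28). Of 24 cholesterol synthesis genes 19 rose and 1 fell, also adjusted over the list alone (median 0.85, adjusted p = 0.000292, and adjusted p = 0.579 with an estimated correlation), with TM7SF2 at 1.90 (SE 0.25) and HMGCS1, an early enzyme of the pathway, at 1.63 (SE 0.44). Of 23 extracellular matrix genes 15 rose and 0 fell, also adjusted over the list alone (median 0.60, adjusted p = 0.000292, and adjusted p = 0.579 with an estimated correlation), with the collagen gene COL1A1 at 1.66 (SE 0.52). CDKN2B, a CDK inhibitor gene, rose by 1.15 (SE 0.25), whereas CDKN1A (0.97, SE 0.55, adjusted p = 0.148; 0.017 with the replicate block) and MDM2 (0.37, SE 0.38) did not pass. The replicate block joined untreated and treated libraries by a number that did not pair them. Within the 2 sets of libraries the p53 median was 0.78 and 0.17. In all, 3073 genes rose and 4231 fell, and 3730 and 3674 after rescaling.

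In every group 2 of the 3 libraries were nearly alike and the third stood apart. Within a group, reads of the near-alike pair differed with a chi-square per degree of freedom of 4.30 to 8.07, above sampling noise, and those of the other pairs with 32.3 to 93.3, so no library was taken for a copy of another. This does not show that the near-alike libraries came from separate cultures. If they did not, n = 3, the SD and p-values above measure in part a technical spread. The library that stood apart was number 3 in both untreated sorts and number 1 in all 4 drug groups. Deviations from the group means placed untreated libraries 1 and 2 with drug libraries 1, and untreated library 3 with drug libraries 2 and 3. Deviations are relative to each group's own mean, so every group had to fall into both sets, and no direct match between treatments was seen. Correlations of untreated with drug libraries ran from -0.39 to 0.34. If the 2 sets are shared between treatments, drug and untreated groups hold unequal parts of them. Values within each set are therefore given beside the drug effects above.

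**Figure D3:**
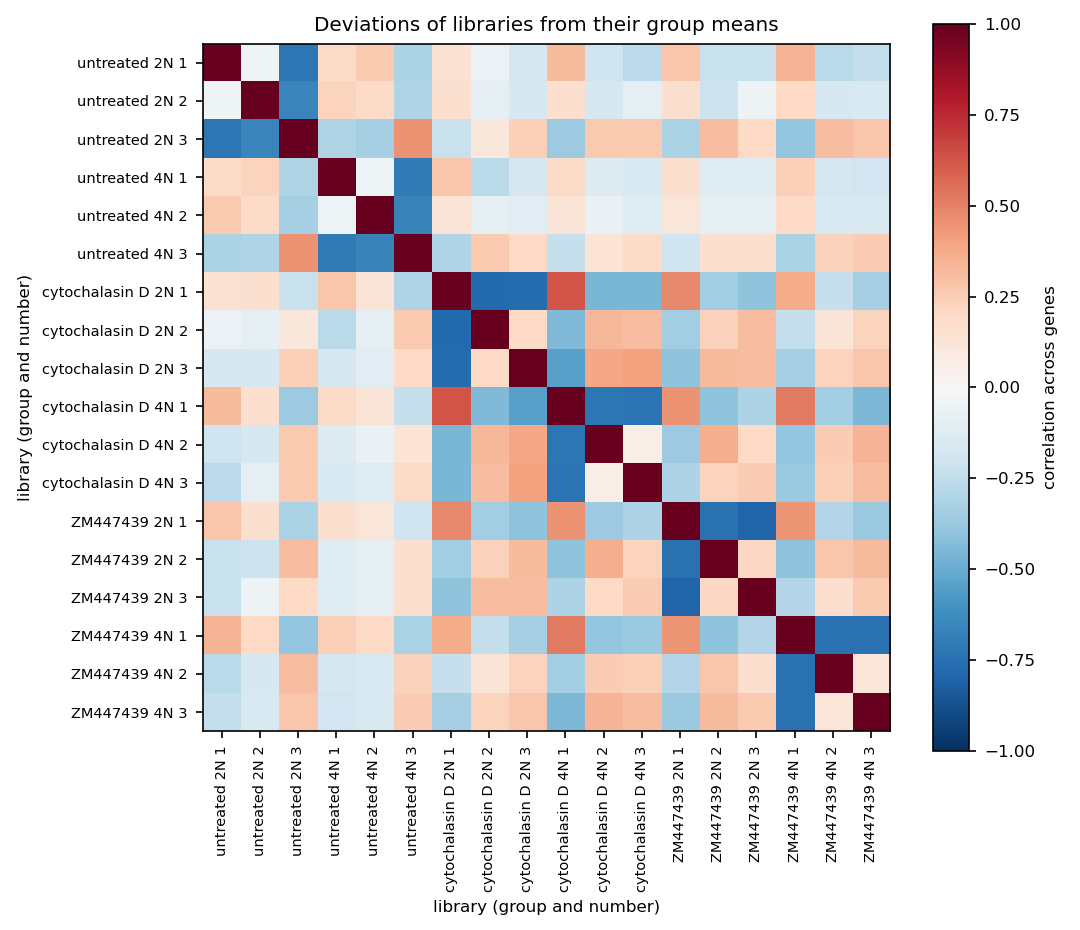
Correlation across genes of the deviations of each library from its group mean, for all pairs of the 18 libraries. Libraries of the same treatment and number correlate at 0.19 to 0.63 between the 2N and 4N sorts, and libraries numbered 1 of both drugs correlate with each other at 0.48 in 2N and 0.52 in 4N cells.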

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

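The interaction tests and the splits of the libraries below were chosen before the data were examined; the culture block and the fits without both libraries of a number were chosen after. All adjusted p values are from limma with BH adjustment, or from camera for lists. The results here are those in which the difference between 4N and 2N cells itself differed between treatments. CCNE2 and CCNF averaged 0.819 and 1.09 RPKM over all libraries. Their differences between 4N and 2N cells are therefore understated in groups where their level is low, which can add to an interaction.

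Between cytochalasin D and untreated cells, 1023 genes passed. Genes of S-phase entry had a higher 4N against 2N difference with drug: UNG by 1.65, CCNE2 by 1.34 and E2F1 by 0.711. Genes that rise towards mitosis had a lower one: UBE2C (-1.81), CCNF (-1.67), AURKA (-1.41) and AURKB (-1.19), as had the CDK inhibitor genes CDKN2D (-1.71) and CDKN2C (-0.819). CCL2 was higher by 1.12. The median was -0.958 for 49 G2/M genes and 0.306 for 32 G1/S and replication genes (adjusted p = 0.523 for both with an estimated correlation; fry adjusted p = 0.00595). With RPM the G2/M median was -0.786, and 13 of 55 genes in place of 35 of 49 were lower. AURKA did not pass with a pseudocount of 0.1 (-1.27, adjusted p = 0.0833) or with RPM (-1.18, adjusted p = 0.123), nor AURKB with a pseudocount of 0.1 (-1.05, adjusted p = 0.051). Of 100 drawn splits, in which 2N and 4N libraries were exchanged inside each treatment, 7 gave as many genes (real 1023, highest other 1881). The count followed the untreated labels: the 12 splits that kept them, the real one included, gave 853 to 1881 genes and the others at most 1. The splits therefore do not decide whether chance can be excluded for the difference between treatments.

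Between ZM447439 and untreated cells, 1317 genes passed. UNG was higher by 1.59, CCNE2 by 1.01 and E2F1 by 0.631, and lower were UBE2C (-1.7), CCNF (-1.68), CDK1 (-1.68), HJURP (-1.61), CDKN2D (-1.6), AURKB (-1.2), AURKA (-0.946) and CDKN2C (-0.716). In the other direction from most G2/M genes, KIF20A was higher by 1.39 and PTTG1 by 1.01. IL1B (1.04) and XPC (0.754) were higher, and ACTG1 (-0.468), PDLIM7 (-0.689) and GAA (-0.562) lower. The list medians were 0.328 for p53 targets, -0.668 for G2/M genes, 0.351 for G1/S and replication genes, -0.438 for SRF-MRTF and actin cytoskeleton genes and -0.211 for lysosome and autophagy genes. With an estimated correlation, adjusted p = 0.875 for G1/S and replication genes and adjusted p = 0.919 for the other 4. With RPM the G2/M median was -0.492, and 12 of 55 genes in place of 28 of 49 were lower. Of 100 drawn splits, 4 gave as many genes (real 1317, highest other 2187). Here too the 12 splits that kept the untreated labels gave 553 to 2187 genes and the others at most 2, so the splits do not decide whether chance can be excluded.

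Several of these calls were near the threshold. Without ZM447439 2N replicate 2, adjusted p was 0.0586 for AURKA, 0.105 for KIF20A, 0.108 for PTTG1, 0.0806 for IL1B, 0.0958 for XPC and 0.0591 for GAA. Each of these 6 was also lost without ZM447439 4N replicate 2 (0.0624, 0.1, 0.109, 0.0518, 0.0606 and 0.0521), without ZM447439 4N replicate 3 (0.0645, 0.11, 0.11, 0.0651, 0.0538 and 0.0607), and in some fits that left out an untreated library. With culture as a block, AURKA (adjusted p = 0.0506), KIF20A (0.0887) and PTTG1 (0.0966) did not pass. ACTG1 did not pass after quantile normalization (-0.246, adjusted p = 0.134). Without both untreated libraries numbered 3, UBE2C (-1.38, adjusted p = 0.0562) and CDK1 (-1.44, adjusted p = 0.053) did not pass.

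Between the 2 drugs no gene passed (limma, 0 genes; 753 at an unadjusted p under 0.05), but 9 lists did in camera. The medians, cytochalasin D minus ZM447439, were -0.303 for G2/M genes, -0.209 for p53 targets, -0.109 for heat shock genes, 0.213 for both SRF-MRTF and actin and cholesterol synthesis genes, 0.105 for lysosome and autophagy genes, 0.163 for extracellular matrix genes, 0.0271 for ribosomal protein genes and 0.188 for retinal pigment epithelium markers. With an estimated correlation, adjusted p was 0.438 for the last list and at least 0.967 for the others, and with culture as a block the ribosomal list did not pass (adjusted p = 0.076). In that fit the immediate early and NF-kB lists passed, both down (camera adjusted p = 0.000347 and 0.0491, and 0.284 and 0.55 with an estimated correlation). Over the list alone, 15 p53 targets were lower and 0 higher, and 6 SRF-MRTF and actin genes were higher and 0 lower. With RPM the p53 median was -0.351 and that of retinal pigment epithelium markers 0.071, which did not pass (adjusted p = 0.104). All 100 of 100 drawn splits gave as many genes (real 0, highest other 962). With a real count of 0 this holds for any split and says nothing about chance. The splits with 962, 901 and 404 genes parted the ZM447439 libraries by their real sorts, and 1 with 318 genes did so for neither drug.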

How the results depend on the processing

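RPM, the culture block, both together, the block of 2 sets and the fits without both libraries of a number or without the 6 that stood apart were chosen after the data were seen; the other 28 settings were planned. Counts are listed in the order in which the report gives the comparisons, for those that moved by more than 1.5 times.

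Both rescalings, both pseudocounts and the replicate block over all libraries kept each of the 11 counts within 1.5 times. With no filter (45103 genes tested), the counts were 3652 (untreated 4N against 2N), 13 (cytochalasin D), 16881, 11579, 15635 and 11487 (cytochalasin D and ZM447439 against untreated in 4N, then in 2N cells), 1585 (cytochalasin D interaction) and 4 (interaction between drugs). With a mean of at least 2 RPKM (6418 genes) they were 875 (untreated), 4709, 3621, 4530 and 3806 (drugs against untreated), 3148 (between drugs in 4N cells), and 338 and 481 (interactions with untreated). More or fewer genes were tested in these fits. In fits of the compared libraries alone, 4N against 2N gave 1 gene for cytochalasin D and 0 for ZM447439 (limma, 2162 at an unadjusted p under 0.05).

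With RPM (20106 genes), the counts were 4097, 1 and 1534 (4N against 2N: untreated, cytochalasin D, ZM447439), 14520, 11485, 13709 and 11313 (drugs against untreated), 8740 (between drugs), and 1662 and 2261 (interactions with untreated). With culture as a block they were 3 and 2019 (4N against 2N, cytochalasin D and ZM447439), and 1924 and 2505 (interactions). With RPM and culture as a block they were 6642, 126 and 4381 (4N against 2N), and 4015, 5153 and 10 (interactions). With the 2 sets as a block they were 2092 (ZM447439 4N against 2N), 1798 and 2374 (interactions); these sets were drawn from the same values. The cause of these differences was not tested.

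Without the 6 libraries that stood apart, the counts were 3915, 941 and 5252 (4N against 2N), and 2768, 4870 and 1621 (interactions). In these fits 2 near-alike libraries per group remained, so the spread may be too small, and set and treatment coincided. Without both ZM447439 libraries numbered 1, 2758 genes passed (4N against 2N), and 2689 and 443 in the interactions with untreated cells and between drugs. Without both untreated libraries numbered 3 the counts were 1218 (4N against 2N), and 565 and 719 (interactions). With single libraries left out, the counts ranged from 0 to 5 (4N against 2N, cytochalasin D; highest without 2N replicate 1), from 208 to 2722 (ZM447439; without 2N replicate 2 and without 2N replicate 1), from 784 to 2429 (ZM447439 interaction; without 4N replicate 3 and without 2N replicate 1) and from 0 to 267 (between drugs; highest without ZM447439 2N replicate 1). The other 7 counts stayed within 1.5 times.

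The covariance of the 2 drug effects in 4N cells, 0.296, was 0.446 and 0.218 with pseudocounts of 0.1 and 1 and 0.361 with a mean of at least 2 RPKM; the first 2 follow from the scale of the logarithm.

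Of 288 pairs of a named gene and a comparison, 1 reversed: MDM2, ZM447439 against untreated 2N cells, was -0.268 without the 6 libraries that stood apart. The calls lost were most often lost in fits of the compared libraries alone (29 pairs), without ZM447439 4N replicate 2 or 3 (22 each) and without ZM447439 2N replicate 2 (20).

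Of 88 list calls without a block, 0 passed with an estimated correlation. With fry, 51 passed and 37 did not. After quantile normalization 68 passed, 17 did not and 3 reversed; with RPM 81 passed, with the replicate block 87. With culture as a block 14 further list tests passed, and between 4N and 2N cells under cytochalasin D the YAP-TEAD and immediate early lists passed with an estimated correlation too (adjusted p = 0.0408 for each). Ribosomal protein genes pointed down, but up after quantile normalization, between 4N and 2N cells under cytochalasin D (adjusted p = 0.436), with cytochalasin D (0.922) and ZM447439 (0.00919) against untreated 4N cells, and in the ZM447439 interaction (0.000202). Mitochondrially encoded transcripts pointed up, but down after quantile normalization, with ZM447439 in 2N cells (0.931), and retinal pigment epithelium markers up, but down with fry, with ZM447439 in 4N cells (0.019). The cause was not tested. Depth limited some genes: counting error made up more than 50% of the residual variance in 18.5% of 12135 genes with a span.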

Other observations

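The splits of the libraries, the main comparisons and the gene lists with their tests were planned before the data were examined. So were quantile normalization, rescaling and leaving out single libraries. RPM, the blocks by culture and by set, and the fits without several libraries were chosen after the data were seen. The other tests in this part, and the use of any fit to weigh an explanation, were chosen after the patterns were seen. Adjusted p values are from limma with BH adjustment, or from camera for lists.

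Some further gene groups changed with both drugs. H2BC21, a histone H2B gene, rose from 0.565 ± 0.297 RPKM in untreated 4N cells to 3.88 ± 1.17 with cytochalasin D (log2 change 2.05, adjusted p = 9.99e-06) and to 2.89 ± 1.12 with ZM447439 (1.67, adjusted p = 0.000137). Of 10 replication-dependent histone genes in 4N cells, 8 rose with cytochalasin D (adjusted p = 0.00214, and adjusted p = 0.635 with an estimated correlation) and 7 with ZM447439 (adjusted p = 0.00692, and adjusted p = 0.591 with an estimated correlation), while 0 fell. Only polyadenylated RNA was measured, so these values cover polyadenylated transcripts of 10 of the 32 listed genes and not their whole output. FOSL1, a subunit of the AP-1 transcription factor, fell by 1.85 and 1.40, although of 25 immediate early genes only 3 rose and 4 fell with cytochalasin D, and 1 and 5 with ZM447439 (camera adjusted p = 0.348 and 0.947). RDH5, a retinol dehydrogenase of the visual cycle, rose by 1.05 and 0.65, and PMEL, a pigment granule gene, fell by 2.24 and 1.54. The PMEL body overlaps CDK2 on the opposite strand, at a mean of 6.1 RPKM against 1.95 for PMEL. CDK2 itself fell by 2.81 and 1.81, and reads of the 2 genes may not be told apart, so the fall of PMEL is uncertain. KRT8, a keratin gene, fell by 0.75 with cytochalasin D (limma, adjusted p = 0.0149), but did not pass after quantile normalization (adjusted p = 0.0881), without untreated 4N replicate 1 (0.0617) or 2 (0.0503), or without cytochalasin D 4N replicate 2 (0.0542) or 3 (0.0536). Of 8 retinal pigment epithelium markers 4 rose and 3 fell with cytochalasin D (camera adjusted p = 0.423), and 1 rose and 1 fell with ZM447439 (camera adjusted p = 0.845).

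Among 21 glycolysis and hypoxia genes in 4N cells, 6 rose and 11 fell with cytochalasin D (camera adjusted p = 0.689), and 4 rose and 10 fell with ZM447439 (0.691). The angiogenic factor gene VEGFA rose by 2.05 with cytochalasin D and 1.37 with ZM447439, while with cytochalasin D the glycolytic genes ENO1 and PFKP fell by 1.32 and 1.12. Of 13 mitochondrially encoded transcripts, 4 rose with cytochalasin D (adjusted p = 0.0313, 0.102 with RPM, and adjusted p = 0.673 with an estimated correlation) and 3 with ZM447439 (adjusted p = 0.0371, 0.115 with RPM, and adjusted p = 0.807 with an estimated correlation). MT-CO1, a subunit of cytochrome oxidase, rose by 0.57 with cytochalasin D (adjusted p = 0.23 after quantile normalization). Drug-treated 4N cells had lower G2/M genes than even untreated 2N cells, with medians of -1.35 for cytochalasin D (47 of 49 lower) and -0.665 for ZM447439 (40 of 49 lower).

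No gene passed between 4N and 2N cells under cytochalasin D (limma, 0 genes; 682 at an unadjusted p under 0.05, and 1411 with culture as a block). A wider spread from the libraries numbered 1 was tested: without both of them 0 genes passed, without cytochalasin D 2N replicate 1 alone 5, and without the 6 libraries that stood apart in all groups 941. The spread was pooled over all 18 libraries, so a gene had the same SE in every treatment, such as 0.242 for MKI67. A wider spread of cytochalasin D libraries therefore cannot account for fewer calls than under ZM447439. The near-alike pairs left in the last fit may understate the spread. Whether the libraries numbered 1 hid differences under cytochalasin D therefore stays open. The 4N against 2N difference of G2/M genes was lower than in untreated cells (median -0.958, fry adjusted p = 0.00595, and camera adjusted p = 0.523 with an estimated correlation), but also under ZM447439 (median -0.668, fry adjusted p = 0.0483), where 998 genes passed. This test partly restates the pattern, so a smaller step in cell-cycle genes between the sorts stays open too, and whether 4N cells under cytochalasin D were in G1 was not measured.

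Heat shock genes were lower with both drugs in both sorts. An unequal share of the 2 sets of libraries may have lowered them, but inside each set, where 1 of the 2 arms holds 1 library, the median nearest to 0 was -0.35. With the 2 sets as a block over all 18 libraries it was -0.459 (fry adjusted p = 3.82e-07, and camera adjusted p = 0.361 with an estimated correlation), which argues against this as the whole cause. The authors' scaling was examined by rescaling the libraries, and the median nearest to 0 was then -0.542. Heat shock genes thus fell relative to the median gene. The medians over all genes were -0.126 and -0.0716 in 4N cells and -0.077 and -0.0376 in 2N cells, for cytochalasin D and ZM447439. Rescaling could move the list only by about as much, and whether the median gene itself changed was not measured. The part of scaling in the fall was therefore not decided. Lower growth or a direct effect of the drugs stays open and was not tested.

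In every group 2 of the 3 libraries were nearly alike. The lowest chi-square per degree of freedom of such a pair was 4.3, which argues against the same library deposited more than once. By implied size, the library that stood apart was the deepest in 1 of 6 groups, which argues against depth of the library that stands apart as the cause. The 2N and 4N libraries that stood apart carried the same number in 3 of 3 treatments, as a culture or library batch not given in the labels would need, and such a batch may be a candidate explanation. No biological explanation was tested.

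Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For untreated 4N against 2N cells 1 of the 10 splits, the real one, gave as many genes (real 2272, highest other 0), for ZM447439 1 (998, highest other 3), and for cytochalasin D 10 (0, highest other 0). For each drug against untreated cells 1 split gave as many, with the highest other 0 (real 9191 and 7190 in 4N cells, 8688 and 7304 in 2N cells), as for cytochalasin D against ZM447439 in 4N cells (5672, highest other 0). Where the groups do differ, the other splits mix them and so widen the residual spread, which lowers their counts. These splits therefore do not decide whether chance can be excluded.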
